A study of Homo sapiens with 6 samples.

How the data were processed

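RNA sequencing libraries were made from MCF10CA1a cells, a malignant line derived from the MCF10A human breast epithelial lineage, grown on hydrogel-coated dishes of 500 Pa or 8000 Pa. Per the labels' protocols, the gels carried growth factor-reduced Matrigel at 0.14 mg/ml, the medium was changed on day 4 and RNA was taken with TRIzol on day 5. The labels call the RNA cytosolic and describe 3 biological replicates per stiffness, numbered 1 to 3. Samples were grouped by the stiffness in their labels, giving 2 groups of 3 libraries.

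For each library the authors deposited 1 table of 26484 gene symbols with a raw count and a log2 value per gene. The counts are whole numbers that are not normalized, and per the submitters' processing notes HISAT2 2.1.2 and HTSeq 0.11.4 were used with the GRCh38 build. The same notes name limma and DESeq2. Strandedness, the kind of RNA selection, the annotation release and the handling of reads that fit several places are not given in the sources used here. The tables list no mitochondrially encoded gene of the fixed list and no row of unassigned reads, so neither share was computed. The log2 values are the authors' TMM-scaled log2 expression per the file headers, and they are filled in for 8593 genes, those with a count above 100 in at least 1 library. For the 7257 of these genes with at least 50 counts in every library, they differed from TMM log2 CPM computed here by at most 0.00924. The remaining genes were not compared. Value columns belonging to no sample of the series numbered 0.

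The counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 11517. Libraries were scaled by TMM, and stiffness was tested with the quasi-likelihood F test and Benjamini-Hochberg adjustment at an FDR of 0.05. CPM values are TMM-scaled and are given as mean ± SD over 3 libraries, and fold changes are log2 of 8000 Pa over 500 Pa with the model's standard error. The main design had stiffness alone. The alternative with the replicate number as a block, called the paired fit, was fixed alongside it. In each same-numbered pair the deviations from the group means were correlated across genes, at 0.409 for replicate 1, 0.184 for replicate 2 and 0.516 for replicate 3, each above the 0.1 required. Among different numbers, 500 Pa replicate 2 with 8000 Pa replicate 1 reached 0.199. The pairing therefore comes from the labels' numbers and this check, not from a stated shared day. The paired fit leaves 2 residual degrees of freedom per gene, and edgeR estimated an infinite prior degree of freedom, so its p-values rest on 1 spread trend shared by all genes.

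Before the data were examined, 43 gene lists were fixed, covering mechanical and matrix genes, cell identity, metabolism, stress, proliferation, signalling and markers of other cell types. The 39 lists with at least 5 tested members were tested with camera from limma 3.58.1 at the preset correlation of 0.01, and again with an estimated correlation and with fry. Further adjusted values within each list are described as adjusted over the list alone. Genes were named by a rule also fixed beforehand. It takes the 8 higher and 8 lower genes of largest fold change that passed with at least 5 CPM in the higher group and no overlap between groups, then the 4 of smallest p each way. From each list it takes up to 3 passing members or, failing these, up to 2 as values. It always includes CCN1 (CYR61), CCN2 (CTGF), ANKRD1 and NODAL. The rule was applied to both fits, and genes named outside it were chosen after their values were seen. Gene symbols are those of the deposited tables. Coordinates, transcript length and GC content come from GENCODE 29 on GRCh38, in which 95.5% of the tested genes were found by symbol.

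Shares of reads were compared by a two-sided exact permutation test, in which 3 against 3 libraries cannot give p below 0.1. Library totals ran from 8305601 to 18779742 counts, and 3 counts, the floor used for a count of 0, equal 0.160 to 0.361 CPM. Intervals and floors of this kind cover counting error only. No pair of libraries agreed within sampling noise, since the chi-square per degree of freedom of their counts was 11.0 or more, so all 6 were kept. The steps were tested on simulated data made from these libraries with 11374 genes. There the unpaired fit recovered 1% of genes changed 2-fold and 75% of those changed 4-fold, and the paired fit recovered 48% and 100%. False calls numbered 0 of 76 unpaired and 4 of 152 paired, and none of 40 random lists passed (0 called). The simulation drew genes independently around replicate effects, with the dispersions of the paired fit. It therefore favoured the paired fit and held no correlation between genes beyond those effects. The changed genes were drawn only from genes above a set average abundance, so the recovery rates do not cover genes of lower level. Nor do the simulation's rates cover correlated genes or a GC trend within 1 pair of the kind seen in pair 1 here. Alternatives covered scaling factors, low-count filters, DESeq2 1.42.0, limma-voom, glmTreat, robust dispersion, thresholds, protein-coding genes only, thinning, GC offsets, left-out libraries, and other set tests. Offsets for transcript length, limma on the deposited log2 values and further versions of the paired fit were chosen after seeing the data. The GC and length trends were fitted to values scaled by library size and then added to the TMM factors. These offsets therefore also shifted all genes together.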

Results

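Gene expression was measured by RNA sequencing in MCF10CA1a cells after 5 days on soft (500 Pa) or stiff (8000 Pa) Matrigel-coated hydrogels, with 3 biological replicates per stiffness. Total counts were 18779742, 8526378 and 8305601 in the 500 Pa libraries and 10360236, 9068926 and 10739449 in the 8000 Pa libraries. The most abundant transcripts were those of GAPDH, the lysosomal protease CTSD and the actin ACTB, followed by PSAP and the keratins KRT8 and KRT15. The first principal component held 49.1% of the variance. It set 8000 Pa replicate 1 at -62.3 apart from the replicate 3 libraries at 47.8 (500 Pa) and 35.4 (8000 Pa). Its gene loadings followed transcript GC content, with a Spearman rho of 0.79 across 11003 genes, which are not independent replicates.

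**Figure D1:**
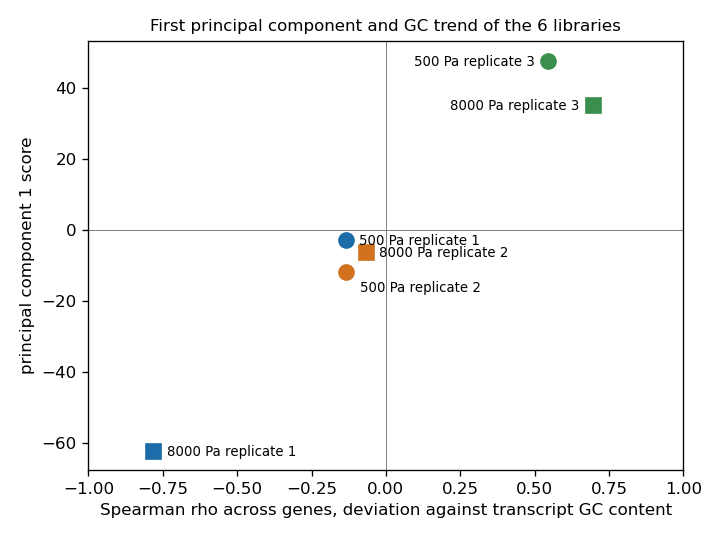
Score of each of the 6 libraries on the first principal component of log2 CPM (y axis, no unit) against the Spearman rho across genes between the library's deviation from the mean and transcript GC content (x axis, no unit). With circles for 500 Pa, squares for 8000 Pa and colours for replicate numbers, 8000 Pa replicate 1 lies at a rho of -0.78, and the replicate 3 libraries lie at 0.55 and 0.70.

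The comparison asked which transcripts differ between cells on a soft and on a stiff matrix. In the paired fit, stiff gels went with higher DMBT1, a secreted mucosal defence glycoprotein, at 763 ± 255 CPM against 231 ± 90.4 on soft gels (log2 fold change 1.73, SE 0.25, adjusted p = 1.70e-08 by edgeR, n = 3 each). The matrix glycoprotein FN1 was also higher, at 90.7 ± 45.9 against 36.0 ± 20.2 CPM. LPL, a triglyceride lipase, stood at 7.96 ± 3.51 against 1.42 ± 0.268 CPM. The interferon-inducible IFI27 was lower on stiff gels, at 1.07 ± 0.366 against 11.3 ± 5.03 CPM (log2 fold change -3.31, SE 0.44, adjusted p = 3.62e-10 by edgeR). HIST1H1D, a linker histone gene, was also lower, at 31.9 ± 24.6 against 89.8 ± 75.8 CPM. Its list of replication-dependent histones had a median log2 fold change of -0.88, with 5 of 21 members passing (camera adjusted p = 5.79e-15, and adjusted p = 0.630 with an estimated correlation). Each of these genes had the same direction in 3 of 3 pairs, but the fit that called them used the same pairs, so this is not separate support.

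The unpaired edgeR fit, the main design, found 0 of 11517 genes at an FDR of 0.05, against 282 at an unadjusted p under 0.05, and its smallest adjusted p was 0.161 (IFI27). DESeq2 found 4 genes without pairing, namely DMBT1, GJA5 and LPL higher and IFI27 lower, and limma-voom found 0. In the paired edgeR fit 61 genes passed, 30 higher and 31 lower at 8000 Pa, with 1222 at an unadjusted p under 0.05. Of the 61, 59 moved the same way in all 3 pairs and 45 changed at least 2-fold, and 39 also passed in paired DESeq2. Agreement of the pairs is partly assured by calling genes on those same pairs. The groups did not overlap for 26 of the genes called higher and 14 of those called lower. Among all tested genes 6.87% did not overlap, and chance gives 10%.

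Of the genes higher at 8000 Pa, GJA5, which encodes the gap junction protein connexin 40, rose from 8.75 ± 3.27 to 26.4 ± 3.50 CPM in the paired fit (adjusted p = 3.34e-05 by edgeR). A2M, a broad protease inhibitor, rose from 1.45 ± 1.36 to 7.42 ± 5.84 CPM. The ubiquitin ligase gene TRIM31 rose from 1.74 ± 0.864 to 7.43 ± 1.44 CPM, MYBPC1, a myosin-binding protein gene, from 1.24 ± 0.329 to 6.20 ± 2.55 CPM, and the nicotinic acid receptor HCAR2 from 1.89 ± 0.609 to 7.16 ± 2.23 CPM. DMBT1 lies on chromosome 10 from 122560665 to 122643736, FN1 on chromosome 2 from 215360440 to 215436172 and LPL on chromosome 8 from 19901717 to 19967259 (GRCh38). Of the lower genes, TAGLN, the actin-binding protein transgelin, fell from 34.7 ± 21.9 to 10.5 ± 4.24 CPM, with an adjusted p of 2.20e-05 by edgeR. IFI27 lies on chromosome 14 from 94104836 to 94116698 and TAGLN on chromosome 11 from 117199321 to 117204782. The unnamed locus LOC284454 fell from 9.12 ± 3.87 to 3.16 ± 1.04 CPM, but it did not pass without any 1 of the pairs, in DESeq2 or with length offsets, and without replicate 1 its log2 fold change was -0.93 in place of -1.51. RPS18, a ribosomal protein gene, fell from 13.9 ± 9.57 to 4.45 ± 1.71 CPM, and it has near-identical copies elsewhere in the genome, so its counts are uncertain.

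Of the replication-dependent histones, which package newly made DNA, all 21 tested members had a log2 fold change below 0 in both fits, and the medians in the 3 pairs were -0.99, -0.50 and -0.85. Without 500 Pa replicate 3 the unpaired median was -0.41 in place of -0.86. Camera gave an adjusted p of 3.81e-12 unpaired and 5.79e-15 paired, and an adjusted p of 0.533 and 0.630 with an estimated correlation. In the paired fit 5 of the 21 fell, and 10 when adjusted over the list alone. Beside HIST1H1D, HIST1H1E fell from 184 ± 160.4 to 70.8 ± 64.1 CPM, and HIST2H2AC from 63.0 ± 42.8 to 25.9 ± 19.6 CPM, with a log2 fold change of -0.84 in place of -1.29 and no call without replicate 1. HIST1H4C, a core histone gene, was the most abundant of those named, at 1686 ± 938 against 745 ± 299.9 CPM. Outside the list HIST1H2AM and HIST1H2AH also fell, and over all tested genes with symbols beginning with HIST, 9 of 43 fell and 0 rose. Histone genes under other symbols were not counted there. Histone genes are a family of near-identical copies, and most of their transcripts lack a poly(A) tail. RN7SK, a small nuclear RNA that also lacks one, fell from 42.9 ± 10.5 to 18.5 ± 9.82 CPM. The list's share of all counts was 0.220% ± 0.101 at 500 Pa and 0.116% ± 0.0342 at 8000 Pa (n = 3 each, two-sided exact permutation p = 0.2).

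**Figure D2:**
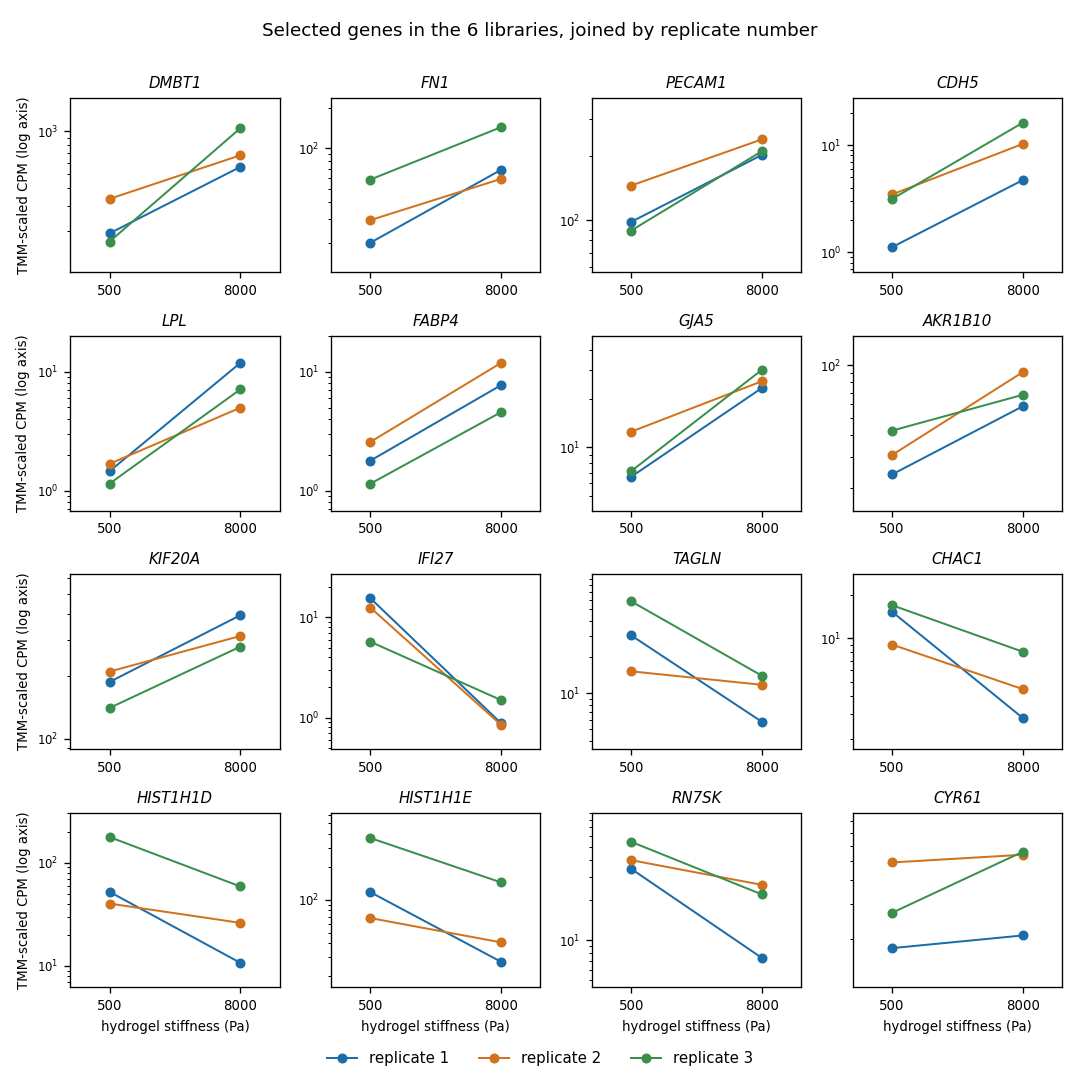
TMM-scaled CPM (y axis, log scale) of 16 genes at 500 and 8000 Pa (x axis, Pa), with 1 point per library and lines joining libraries of the same replicate number. DMBT1 is higher and IFI27 lower on the stiff gel in each of the 3 pairs, while CYR61, plotted for comparison, did not pass.

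Genes of G2/M and mitosis were higher as a group on stiff gels. Of 31 tested members 30 had a fold change above 0, the median was 0.55 unpaired and 0.49 paired, and the medians in the 3 pairs were 0.87, 0.26 and 0.34. Without 8000 Pa replicate 1 the unpaired median was 0.22, and the list still passed camera. Camera gave an adjusted p of 8.61e-12 unpaired and 7.32e-14 paired, and an adjusted p of 0.533 and 0.630 with an estimated correlation. KIF20A, a kinesin of cytokinesis and the 1 member to pass, rose from 180.0 ± 35.9 to 329.5 ± 59.95 CPM in the paired fit, and 10 members rose when adjusted over the list alone. KIF20A did not pass with the GC offset, the length offset or both. The mitotic kinase AURKA had 276 ± 78.1 against 167 ± 24.8 CPM and did not pass. The DNA replication and G1/S list, also of 31 tested genes, had a median of 0.07 and did not pass (camera adjusted p = 0.981), with MCM5 at 324 ± 81.6 against 490.0 ± 131 CPM.

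Cytosolic ribosomal protein genes were lower as a list, with a median of -0.34 in both fits and 28 of 31 members below 0 unpaired. Camera's adjusted p was 1.02e-06 unpaired and 1.49e-06 paired, and the adjusted p was 0.577 and 0.780 with an estimated correlation, and 0 members passed. The medians in the pairs were -0.73, -0.24 and 0.07, and pair 1 also showed a Spearman rho of -0.62 between fold change and GC content across genes, against 0.06 and 0.02 in the others. Without 8000 Pa replicate 1 the unpaired median was -0.13 (camera adjusted p = 0.0466). These genes took 4.09% ± 0.336 of counts at 500 Pa and 3.44% ± 0.357 at 8000 Pa (two-sided exact permutation p = 0.1, the smallest possible, n = 3 each).

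Endoplasmic reticulum chaperones had a median of 0.38, with 18 of 20 members above 0 and medians of 0.62, 0.11 and 0.51 in the pairs. Camera gave 3.03e-04 unpaired and 1.16e-04 paired, against an adjusted p of 0.533 and 0.630 with an estimated correlation, and 0 members passed. The disulfide isomerase PDIA3 had 703 ± 125 against 442 ± 89.1 CPM, and the chaperone HSPA5 had 749 ± 112 against 519 ± 117 CPM. Targets of ATF4 in the integrated stress response had a median of -0.29 (camera adjusted p = 3.61e-04 unpaired and 0.00131 paired). With an estimated correlation the adjusted p was 0.533 and 0.780. In the paired fit 1 of the 24 fell, CHAC1, a glutathione-degrading enzyme, from 13.8 ± 4.19 to 5.10 ± 2.70 CPM, and 1 when adjusted over the list alone. The medians in the pairs were -0.69, -0.22 and 0.08. Without 500 Pa replicate 1 the list did not pass (camera adjusted p = 0.0689 unpaired).

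Extracellular matrix genes had a median of 0.36 (camera adjusted p = 0.00561 unpaired and 4.71e-04 paired), and 0.533 and 0.630 were the adjusted p with an estimated correlation. Of 24 tested members, FN1 alone rose in the paired fit, also when adjusted over the list alone (1 gene). Their medians in the pairs were 0.40, -0.13 and 0.49. The list did not pass without 8000 Pa replicate 3 (camera adjusted p = 0.205 unpaired), and its unpaired median was 0.18 without 500 Pa replicate 3 and 0.21 without 8000 Pa replicate 1. NRF2 targets had a median of 0.31 (camera adjusted p = 0.0111 unpaired and 0.0278 paired). The adjusted p was 0.533 and 0.630 with an estimated correlation. AKR1B10, an aldo-keto reductase, rose from 32.5 ± 9.38 to 72.7 ± 17.0 CPM as the single passing member of 20, and 3 rose and 1 fell when adjusted over the list alone. The medians of the NRF2 list in the pairs were 0.18, 0.25 and -0.01. Unpaired, the NRF2 list did not pass without 500 Pa replicate 1 (camera adjusted p = 0.0689), 500 Pa replicate 2 (0.304) or 8000 Pa replicate 3 (0.229), and its median was 0.15 without 8000 Pa replicate 1. Hypoxia response genes had a median of 0.29 (camera adjusted p = 0.0243 unpaired and 0.0159 paired, and 0.577 and 0.780 as adjusted p with an estimated correlation). NDRG1, a hypoxia-inducible gene, rose from 13.6 ± 4.65 to 30.1 ± 7.47 CPM, 1 of 20 in the paired fit and 1 when adjusted over the list alone. Those of the hypoxia list were 0.36, -0.14 and 0.38. Unpaired, the hypoxia list had a median of 0.02 and did not pass without 8000 Pa replicate 1 (camera adjusted p = 0.147), nor did it pass without 500 Pa replicate 3 (median 0.20, 0.255) or 8000 Pa replicate 3 (0.165). Stemness genes, of which 8 were tested, had a median of 0.24 (camera adjusted p = 0.0252 unpaired and 0.0167 paired, and 0.533 and 0.630 as adjusted p with an estimated correlation). No member passed over all genes (0 of 8) and 1 did when adjusted over the list alone. The stemness medians in the pairs were 0.64, 0.04 and 0.42. With length and GC offsets the stemness median was -0.02 unpaired and -0.01 paired and the list did not pass (camera adjusted p = 0.132 and 0.147), where the median of all genes was -0.16 and -0.17. Nor did it pass with the GC offset (0.0624 unpaired and 0.0594 paired) or, unpaired, without 500 Pa replicate 1 (0.0689), 500 Pa replicate 3 (median 0.14, 0.205), 8000 Pa replicate 1 (0.113) or 8000 Pa replicate 2 (0.0979), and its median was 0.56 without 500 Pa replicate 2 and 0.39 without 8000 Pa replicate 3. ALDH1A1, an aldehyde dehydrogenase, had 10.2 ± 3.80 against 4.05 ± 0.394 CPM.

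Among genes often tied to matrix stiffness, targets of SRF and its cofactor MRTF had a median of -0.20, with 15 of 21 members below 0. Camera gave 0.0437 unpaired and 0.0278 paired, against an adjusted p of 0.533 and 0.738 with an estimated correlation. TAGLN fell while FHL1, a LIM-domain gene, rose from 1.17 ± 1.37 to 3.95 ± 1.25 CPM, and when adjusted over the list alone 1 rose and 2 fell. FHL1 did not pass with the GC offset, the length offset or both, in paired DESeq2 or with library size alone. The medians of the SRF list in the pairs were -0.48, -0.09 and -0.19. The SRF list did not pass with the GC offset (camera adjusted p = 0.107 unpaired and 0.0643 paired) or with length and GC offsets (0.111 and 0.0843). Unpaired, it did not pass without 8000 Pa replicate 1 (median -0.11, 0.439), 500 Pa replicate 1 (0.0689) or 500 Pa replicate 2 (0.116), and its median was -0.08 without 500 Pa replicate 3. The 19 tested YAP/TAZ-TEAD targets did not pass (median 0.29, camera adjusted p = 0.133 unpaired and 0.0976 paired), and 0 passed singly or when adjusted over the list alone, but the list passed as higher without 500 Pa replicate 2 (median 0.51, camera adjusted p = 0.0186 unpaired). AXL, a receptor tyrosine kinase, had 173 ± 24.6 CPM at 8000 Pa and 279.97 ± 91.0 at 500 Pa. CYR61 (CCN1) had 4.35 ± 1.97 against 3.14 ± 1.61 CPM, with a log2 fold change of 0.48 (SE 0.53), and CTGF (CCN2) had 1.00 ± 0.179 against 1.22 ± 1.08 CPM. ANKRD1 had 4 counts and NODAL 1 count over the 6 libraries, too few to test. Focal adhesion and integrin genes also did not pass, with a median of -0.04 over 24 members and 0 called. Basal keratins and basal markers passed only in the paired fit, with a median of -0.36 (camera adjusted p = 0.0339, and adjusted p = 0.774 with an estimated correlation, against 0.0556 unpaired). None of the 12 passed over all genes (0 called), and 1 rose and 4 fell when adjusted over the list alone. The medians of the basal list in the pairs were -0.84, 0.01 and -0.25. In the paired fit the list did not pass with the GC offset (camera adjusted p = 0.283) or with length and GC offsets (0.146), and without 500 Pa replicate 2 it passed unpaired (median -0.57, 0.00395). The unpaired median was -0.16 without 500 Pa replicate 3 and -0.22 without 8000 Pa replicate 1. KRT17, a basal keratin, had 1209.5 ± 386 against 2249 ± 1001 CPM.

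The lists of other cell types held a few called genes. Of 3 endothelial markers tested, the adhesion molecules PECAM1 and CDH5 rose in the paired fit, from 111 ± 30.4 to 219 ± 19.7 CPM and from 2.58 ± 1.27 to 10.4 ± 5.72 CPM, and ESAM did not pass. VWF, the endothelial clotting factor, stayed at 0 to 0.372 CPM. Of 5 adipocyte and neural markers, LPL and FABP4, a fatty acid carrier, rose, FABP4 from 1.83 ± 0.715 to 8.09 ± 3.69 CPM. The same 2 rose when adjusted over the list alone. The list median was 0.14 unpaired, 0.59, -0.15 and 1.299 in the pairs, and 0.06 to 0.64 with single libraries left out. Camera gave that list 3.61e-04 unpaired and 0.00201 paired, and an adjusted p of 0.533 and 0.630 with an estimated correlation. Of 3 leukocyte markers and 1 fibroblast marker tested, 0 passed, with CD14 at 13.6 ± 6.34 against 8.98 ± 2.28 CPM and COL1A1 at 2.15 ± 1.48 against 1.197 ± 0.678 CPM.

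Among the other lists, single members passed in the paired fit while the list did not. HK2, a hexokinase, rose from 65.2 ± 27.3 to 119 ± 18.9 CPM, and S100A9, a calprotectin subunit, from 64.4 ± 48.4 to 133 ± 51.0 CPM. HK2 did not pass with the GC offset, the length offset or both. Without replicate 2 the log2 fold change of S100A9 was 0.76 in place of 1.202 and it did not pass (adjusted p = 0.196 by edgeR). IFI27 was the only interferon-stimulated gene of 26 to pass, and 19 of the 26 had a paired fold change above 0. Without 500 Pa replicate 3 the interferon list passed as higher (median 0.56, camera adjusted p = 3.46e-09 unpaired). When adjusted over the list alone, 2 interferon-stimulated genes rose and 2 fell, and of 13 antigen presentation genes 1 rose and 4 fell. The lists of mesenchymal, epithelial and luminal markers, cholesterol and fatty acid synthesis, p53, TGF-beta, Notch, Wnt, inflammatory and immediate early genes did not pass, each with a camera adjusted p of 0.106 or more unpaired. Without 500 Pa replicate 2 the fatty acid list passed as higher (median 0.35 in place of 0.20, adjusted p = 0.0133), and the oxidative phosphorylation list passed as lower (0.00545), as it did without 8000 Pa replicate 3 (0.0191). Also passing as lower were antigen presentation (median -0.66 in place of -0.27, 0.0129) and glycolysis (-0.33 in place of -0.06, 0.0277) without 8000 Pa replicate 3, and metallothioneins without 500 Pa replicate 3 (8.21e-06). In all, 11 of 39 lists passed camera unpaired, 7 higher and 4 lower, and 12 paired, 7 higher and 5 lower. With an estimated correlation 0 passed. In 12 of the 28 lists that did not pass unpaired, the median, mean and camera direction differed in sign.

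**Figure D3:**
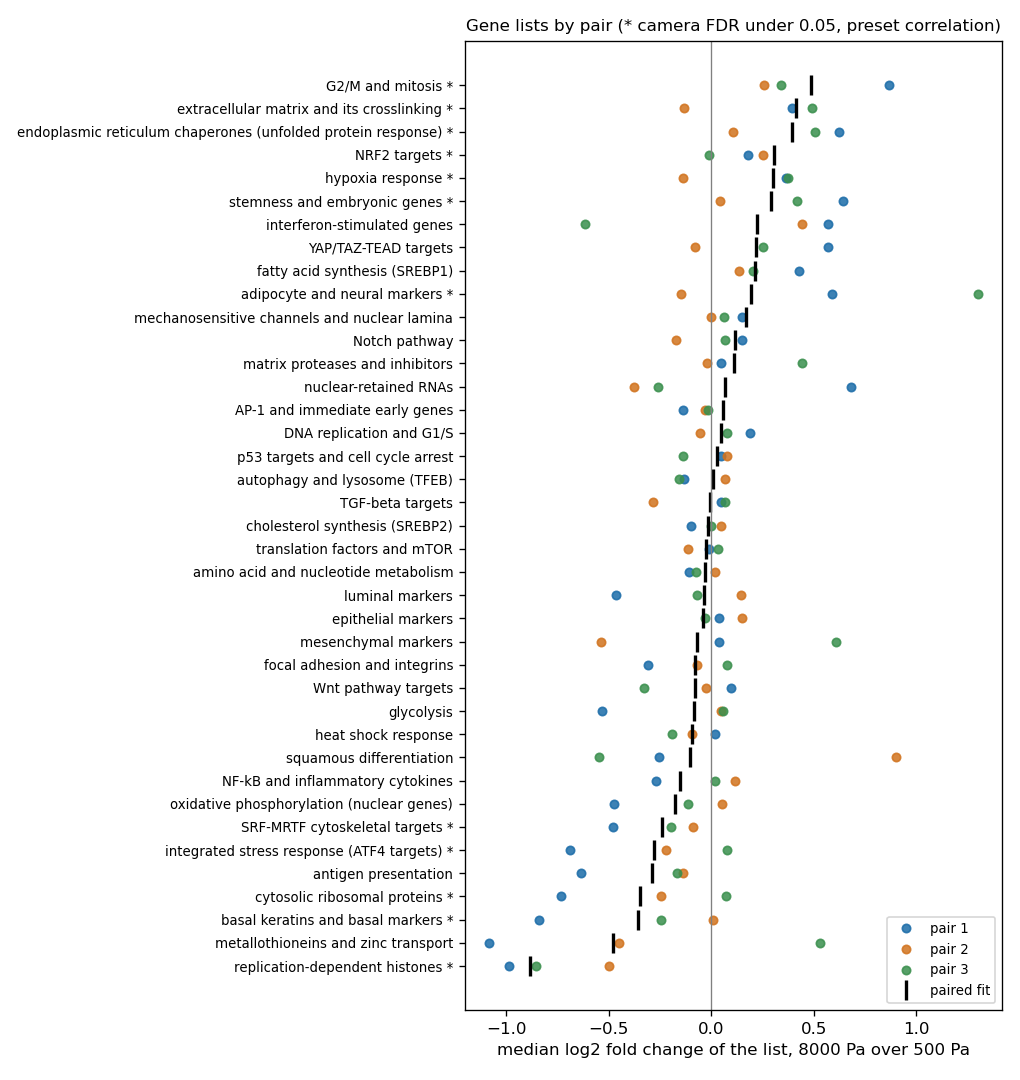
Median log2 fold change of 8000 Pa over 500 Pa (x axis, log2) for the tested members of 39 gene lists (y axis), with coloured points for the 3 same-numbered pairs, black bars for the paired fit, and asterisks for lists passing camera at the preset correlation in the paired fit. Histones lie below 0 and mitotic genes above 0 in all 3 pairs, and ribosomal protein genes run from -0.73 to 0.07.

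Of the 61 paired calls, 30 passed without the replicate 1 pair, 46 without replicate 2 and 6 without replicate 3, and LPL and IFI27 were the only genes (2) to pass each time; the totals without those pairs were 38, 81 and 12. Of the called genes named here, CHAC1, FHL1, HIST1H4C, HIST2H2AC, HK2, RPS18 and LOC284454 did not pass without replicate 1, AKR1B10, FABP4, HCAR2, KIF20A, MYBPC1, S100A9, TRIM31 and LOC284454 did not pass without replicate 2, and without replicate 3 those that passed were FABP4, IFI27, LPL, MYBPC1 and TRIM31. The paired fold change rose with transcript length across genes (Spearman rho 0.32) and fell with GC content (-0.37). Both trends lay mostly in pair 1, and the rho for length was 0.42, 0.03 and 0.09 in the 3 pairs. Length offsets with the replicate block left 26 calls, GC offsets gave 93 (26 higher, 67 lower), and scaling by library size alone, which raised the median of all genes to 0.16, gave 41 (32 higher, 9 lower). The GC and length offsets lowered that median to -0.17 and -0.16, since they came on top of the TMM factors. Their counts by direction, and the loss of KIF20A, HK2 and FHL1, therefore cannot be put down to GC or length alone.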

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

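The paired versions other than the replicate block itself and the GC offset with it, the length offsets and limma on the deposited log2 values were chosen after seeing the data. Without pairing, edgeR called 0 genes under most alternatives. No low-count filter gave 8 (6 higher, 2 lower), DESeq2 gave 4 (3 higher, 1 lower), the GC offset gave 1 (lower, IFI27), and leaving out single libraries gave 0 to 1, the 1 being IFI27 without 500 Pa replicate 3. DMBT1, LPL and IFI27 were among the 8 and were also paired calls. The replicate block gave 61 (30 higher, 31 lower), and with the GC offset 93 (26 higher, 67 lower, 47 shared with the 61). Within the paired fit, glmTreat against a fold of 1.5 gave 13 (8 higher, 5 lower) and an FDR of 0.01 gave 32 (16 higher, 16 lower), both stricter by construction. Length offsets gave 26 (12 higher, 14 lower), all 26 shared, and length with GC offsets gave 33 (17 higher, 16 lower, 29 shared). All these offsets also lowered the median of all genes, so the counts by direction do not reflect the trends alone. Library size alone gave 9 lower genes, no filter 46 higher, DESeq2 20 lower, and limma on the deposited log2 values 47 lower; the cause was not tested. Leaving out 1 pair gave 12 to 81 genes (8 to 43 higher, 4 to 38 lower), with fewer samples in each fit. The remaining paired alternatives gave 41 to 89 genes. Of 31 named genes that passed in the paired fit, 22 passed with length and GC offsets and 27 in DESeq2, and none of the 31 changed sign under the alternatives run.

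For gene lists, the unpaired total of 11 became 0 (0 higher, 0 lower) with an estimated correlation and 0 with fry (0 higher, 0 lower). It ranged from 7 to 14 with 1 library left out (4 to 8 higher, 2 to 7 lower). With the block, 7 lower lists passed under RLE factors, 7 under upper-quartile factors and 7 without the filter, against 5. The squamous differentiation list, which did not pass, had a median of -0.44 and camera's direction reversed to lower without 500 Pa replicate 2 (adjusted p = 0.0162), and it passed as higher without 500 Pa replicate 3 (median 0.28, adjusted p = 6.06e-06). With the block and library size alone the SRF list had a median of -0.07 and did not pass (adjusted p = 0.0528), nor did it unpaired without the low-count filter (median -0.11, 0.0525), and with the length offset unpaired neither it (0.0961) nor the stemness list (0.0541) passed. With the block, the fatty acid synthesis list passed under RLE factors (adjusted p = 0.0487), upper-quartile factors (0.0474), library size alone (0.0210), no filter (0.0321) and the GC offset (0.0430). The oxidative phosphorylation list passed under RLE factors (0.0447), upper-quartile factors (0.0474), no filter (0.0331) and the GC offset (0.0180). Antigen presentation passed under RLE factors (0.0447), upper-quartile factors (0.0468) and library size alone (0.0291), and metallothioneins without the filter (0.0464). Squamous differentiation passed with the length offset (0.0332) and both offsets (0.00277), and unpaired with both offsets (0.0148), and basal keratins passed unpaired under library size alone (0.0221). The replicate block changed no other list call than that of basal keratins. Library size alone put the median of all genes at 0.17 unpaired, and the offsets for GC and length put it between -0.14 and -0.17. Relative to the median of all genes the histone, mitotic and ribosomal protein medians kept their signs under every scaling and offset run with the block. Thinning every library to the smallest left 54 paired calls, 44 of them shared with the 61, and ANKRD1 and NODAL had too few counts to test at any depth used here.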

Other observations

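The tests reported here on added lists, technical explanations and hypotheses were chosen after the results they bear on were seen, except the counts over other splits of the samples; this includes the markers and bounds used for other cell types. Genes named here outside the naming rule were likewise chosen after their values were seen.

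BPIFB1, a secreted airway protein of the bactericidal/permeability-increasing family, was the 7th most abundant transcript, at 12299 ± 5491 CPM on soft and 6342 ± 2342 CPM on stiff gels. It was lower in 3 of 3 pairs and did not pass (paired log2 fold change -0.95, SE 0.28, adjusted p = 0.0867 by edgeR). MUC5B, an airway mucin, stood at 417 ± 155 and 435 ± 220 CPM, whereas the mesenchymal filament gene VIM had 30.1 ± 1.91 and 27.1 ± 9.85 CPM. Of 21 tested secreted airway and gland defence genes, DMBT1 rose and BPIFB2, DCD and LACRT fell in the paired fit (1 higher, 3 lower). Levels within the list varied widely, and SCGB1A1, a secretory cell gene, had 0.694 and 1.62 CPM. For the whole list limma's camera gave p = 0.0921, and p = 0.477 with an estimated correlation. BPIFB2, another member of the BPIFB1 family, fell from 118 ± 28.0 to 67.8 ± 37.9 CPM, and DCD, the sweat-gland peptide dermcidin, from 19.8 ± 14.4 to 10.7 ± 13.8 CPM. In paired DESeq2 and with the length offset, BPIFB2 and LACRT did not pass. Without replicate 1 none of BPIFB2 (log2 fold change -0.47 in place of -0.90, adjusted p = 0.814 by edgeR), DCD (-1.06) and LACRT (-1.31) passed, without replicate 2 LACRT was at -2.99 in place of -1.78, and DMBT1 and these genes did not pass without replicate 3. The cell cycle inhibitor genes CDKN2A and CDKN2B had 0 counts in all 6 libraries, which allows up to 0.160 to 0.361 CPM per library, and the neighbouring MTAP had 13 counts in all.

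Other called genes outside the lists included PTGS1, a cyclooxygenase, which rose from 8.66 to 20.4 CPM in the paired fit, PADI3, a citrullinating enzyme of epidermis, from 37.1 to 85.2 CPM, and GRHL3, an epithelial transcription factor, from 5.66 to 14.04 CPM. Among the lower ones were UPP1, uridine phosphorylase, from 238 to 128 CPM, GALK1, galactokinase, from 98.6 to 51.0 CPM, and DBN1, the actin-binding protein drebrin, from 72.6 to 39.4 CPM. None of PTGS1, PADI3, GRHL3, UPP1, GALK1 and DBN1 passed without replicate 3, where PADI3 had a log2 fold change of 0.58 in place of 1.03. Without replicate 1 UPP1, GALK1 and DBN1 (-0.54, -0.60 and -0.65) and GRHL3 (1.16) did not pass either, nor GRHL3 without replicate 2. In paired DESeq2 PADI3 and GALK1 did not pass. Of these genes only DBN1 passed with the length offset, and only GRHL3 and UPP1 with length and GC offsets. GALK1 also did not pass with the GC offset.

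The first pattern is the lower level of histone transcripts on stiff gels, a list call lost with an estimated correlation (adjusted p = 0.630 paired). A transcript length and GC trend is argued against as the whole cause, since with offsets for both the list's median stayed 0.59 below that of all genes (-0.59, against -0.88 without offsets; camera adjusted p = 2.25e-09). A lower yield of RNA without a poly(A) tail in the 8000 Pa libraries is a candidate explanation, because all 7 tested RNA polymerase III transcripts were also below 0, with a median of -1.12 (camera p = 9.80e-10, and p = 0.0841 with an estimated correlation). That camera test included RN7SK and RN7SL1, which had passed singly, so its p is not separate from those 2 calls. RN7SL1 did not pass with the length offset, with both offsets or without replicate 1, whereas RN7SK passed in each. BCYRN1 had a paired log2 fold change of only -0.19 (SE 0.64) and was higher in 1 of 3 pairs. The polymerase III list was not tested with the offsets. The 5 members that did not pass singly had a median of -1.09 and were not tested by themselves. Fewer cells in S phase stays open too, since the DNA replication and G1/S list had a paired median of 0.0504 with members going both ways, and an effect of stiffness itself on histone transcripts was not tested apart from these.

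The second pattern is the higher level of PECAM1, CDH5, LPL and FABP4. Endothelial cells in the cultures are argued against, since the upper 95% counting limit (Poisson) of 7 other endothelial markers was 0.0611 of the counts of CDH5 over the 8000 Pa libraries (at most 0.107 in any 1 of them) and lower against PECAM1; ESAM, left out for its level on both gels (5.98 ± 1.68 and 6.14 ± 2.09 CPM), would raise the highest limit for CDH5 to 1.17. Adipocytes are argued against by the same measure, since PLIN1, ADIPOQ and LEP together had a limit of 0.0759 of the counts of FABP4 and 0.0731 of those of LPL, though up to 0.307 for LPL in 8000 Pa replicate 2, where PLIN1 had 8 counts. A length and GC trend is argued against for CDH5, LPL and FABP4, whose log2 fold changes were 1.81 or more with both offsets, and stays open for PECAM1, which went from 1.01 (SE 0.23) to 0.62 (SE 0.20), or 1.02 to 0.79 relative to all genes, and no longer passed (adjusted p = 0.219), in a fit where the adjusted p of LPL also rose, from 6.81e-05 to 0.00585. Expression of these genes by the cancer cells themselves, changed by stiffness, also stays open and was not tested.

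The third pattern is higher mitotic and lower ribosomal protein medians, whose paired camera calls were lost with an estimated correlation (adjusted p = 0.630 and 0.780). A length and GC trend is argued against as the whole cause for both lists, whose medians relative to all genes were 0.49 and -0.34 as reported, 0.49 and -0.20 with the length offset and 0.49 and -0.25 with both offsets. This holds for the list medians only. KIF20A no longer passed with either offset or both, but these also lowered the median of all genes. For the mitotic list the replicate 1 pair was not the only source of the higher median, which was 0.26 and 0.34 in the other pairs. Without that pair the relative median was 0.32 (camera adjusted p = 6.66e-09 at the preset correlation). That p cannot settle whether the rest exceeds chance, since the same test also passed lists in splits that did not follow stiffness. For the ribosomal protein list the replicate 1 pair alone cannot be told apart from an effect of stiffness, since the relative median without replicate 1 was -0.13 (camera adjusted p = 0.0522). An effect of stiffness on proliferation was not tested otherwise.

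A pair of hypotheses on gene groups was tested in the paired fit. LPL, FABP4 and HCAR2 may belong to a wider rise of targets of the lipid-sensing receptor PPAR. The other 20 tested targets had a median of 0.17, with 15 above 0 and 0 called, and camera gave p = 0.00584 at the preset correlation and p = 0.0951 with an estimated one, so this was not settled. SNHG15 fell from 58.1 ± 13.3 to 28.8 ± 7.44 CPM, a call lost without replicate 1 or replicate 3, but the 18 small nucleolar RNA host genes had a median of -0.06 and a p of 0.102 by limma's camera, so a wider fall of that class was not detected.

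The other splits of the samples are too few for a share under 0.05. Over the 10 splits of the 6 libraries into 3 against 3, the unpaired fit called 0 genes in the real split and at most 0 in the others, so 10 of 10 gave as many. Camera passed 11 lists in the real split, the only 1 of 10 to reach that, and 5 to 10 in the others. Lists thus also passed at the preset correlation where the split did not follow stiffness. Of the 4 splits that part every pair, the real one called 61 genes and the others at most 0, so 1 of 4 reached that count. In the same 4 splits camera passed 12 lists in the real one and 5, 6 and 10 in the others.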
